A study of Mus musculus with 23 samples.

How the data were processed

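Total RNA of bone marrow lymphocytes from wild-type mice was profiled in 23 libraries, 5 labelled EILP and 6 each labelled ILCP, NKP and NK. Per the labels' protocols, cDNA was made with the SMART-Seq v4 Ultra Low Input kit and libraries with the Nextera XT kit, which do not mark the strand. The authors deposited raw counts per gene as whole numbers without normalisation, in a table of all populations and a second table of NKP and NK. The 12 columns that both tables share were identical. Per the submitters' processing notes, the genome build was GRCm39 and FastQC was run. The aligner, the counting tool and the annotation release are not given in the sources used here. The reference annotation used here is of an older build, so no coordinates are printed, and it served only to look up transcript lengths.

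The tables hold 56980 genes with Ensembl identifiers. Of these, 1542 had no gene name and were kept under their identifier in library totals, and in tests where they passed the filter. On average they held 0.786% of the counts in EILP, 0.506% in ILCP, 0.385% in NKP and 0.408% in NK. Without strand, reads of overlapping or antisense genes such as Xist and Tsix cannot be told apart. Families of near-identical genes, such as the Klra receptors, the H2-Q genes, the osteocalcin and the haemoglobin genes, may have exchanged reads, and their single members are uncertain.

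Groups came from the sample titles. The labels give no sex of the animals, and no term for sex entered the fits. Nothing in the labels says that the replicates came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical. Between NK 1 and NK 6 it is not only technical, as Xist stood high in the first and the Y-linked Ddx3y in the second. EILP 1 and EILP 4 were closer to each other than any other pair of replicates: the mean chi-square of their counts was 5.51, against 7.73 to 192 for the other 54 pairs. At genes of 20 to 99 counts it was 1.70, against 4.67 to 20.8. The lowest values of the other EILP pairs were 47.5 and 4.92. EILP 1 and EILP 4 still differed by more than sampling noise, which does not show that they are separate samples. They were kept as 2 samples, with their sum as an alternative. If they come from 1 sample, the tests against EILP rest on fewer independent samples than the 5 counted.

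Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with the group design, and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values for genes come from that test. EILP, ILCP and NKP entered 1 fit (17 libraries) and NKP and NK another (12 libraries). The standard error of a log2 fold change was its size divided by the square root of F. Levels are counts scaled to 1000000 per library (CPM) with TMM factors over all 23 libraries, given as mean ± SD, and shares of counts use raw totals. Where a population had no count for a gene, the fold is a lower bound computed with 3 counts over the group, scaled with the same factors as the levels. With 1 to 3 counts no fold is given. These floors cover counting error only. For genes whose populations do not overlap, the chance share is that of the 2 fully separated orderings among all splits of the libraries.

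The 24 tested gene lists, the list of core genes and the list of sex-linked genes were fixed before the data were examined, as were the test, the alternatives planned and the rule for the genes named. That rule named the core genes whatever their result, the 5 highest and 5 lowest called changes per comparison with a mean of at least 20 CPM and no overlap, up to 3 called members per list with a mean of at least 5 CPM, and the most abundant member of each list of other cell types. Some genes that the rule names are not reported here. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. The test fry, planned beside camera, asks whether the genes of a list move on balance 1 way, without comparing them with other genes. It called 15, 20, 15 and 17 of 24 lists for NKP against EILP, ILCP against EILP, NKP against ILCP and NK against NKP. These held every list that camera called, in the same direction, but the ribosomal list of NKP against EILP (fry adjusted p = 0.202). Calls adjusted over the list alone use the same gene tests. One glycolysis symbol matched 2 identifiers, which gave 18 tested genes for 17 symbols. Bglap, Col1a1, Col1a2, Ddx3y, Fgf15, Igkc, Sparc and Trdc, where named outside that rule, were chosen after their values were seen. Lists of osteoblast, chondrocyte, reticular stroma, endothelial, osteoclast and plasma cell genes, and of the neighbours of Fgf3 and Fgf15, were also written after the data were examined.

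On simulated counts drawn from the mean levels, gene dispersions and depths of these libraries, with 100 genes changed 2-fold and 100 changed 4-fold, the test recovered 44% and 95% of these 100 genes for NKP against EILP, 43% and 95% for ILCP against EILP, 48% and 96% for NKP against ILCP, and 36% and 86% for NK against NKP. The genes tested numbered 18354, 18331, 18354 and 16546. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery at lower levels was not measured. False calls were 2.80%, 3.50%, 3.36% and 5.43% of the calls in the same order.

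The alternatives were DESeq2 size factors, library totals, upper quartile factors, no filter on low counts, a mean of at least 5 CPM in a group, glmTreat against a log2 fold change of 1, the DESeq2 1.42.0 Wald test, limma-voom, the 2 compared groups only, the replicate number as a block, and each library left out in turn. Some changed more than the choice named: the DESeq2 Wald test also used DESeq2 size factors, and fits of other libraries filtered the genes anew. Added after the data were examined were the sum of EILP 1 and EILP 4, fits without NKP 1 and NKP 5 or without NK 1 and NK 6, a fit without the 982 genes that stood under 1 CPM in all groups but NKP, TMM factors from genes above 1 CPM in every group, and 1 fit of all 23 libraries. Pseudocounts and filters for normalised values did not apply, as the values are counts. Principal components were computed on log2(CPM + 1), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.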

Results

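RNA from bone marrow lymphocytes of wild-type mice was sequenced in 23 libraries of 4 populations, labelled EILP (n = 5), ILCP (n = 6), NKP (n = 6) and NK (n = 6). In the field these names stand for the early innate lymphoid progenitor, the innate lymphoid cell precursor, the NK cell progenitor and the NK cell. The series used mice carrying reporters of several transcription factors to follow NK cell development in the marrow, and its title ties the early NK cell precursor to Eomes. The gates that defined each population are not given in the labels, and whether a gene reported below also served as a gate is not known here.

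In units of 1000000 counts, the deposited counts summed to 17.7, 18.9, 22.4, 39.3 and 25.4 in EILP libraries 1 to 5, and to 32.2, 22.2, 21.6, 16.6, 17.6 and 15.0 in ILCP libraries 1 to 6. NK libraries 1 to 6 held 40.9, 20.9, 20.9, 19.5, 21.7 and 17.3. NKP libraries were shallower and less even, with 5.82, 22.2, 1.33, 29.5, 6.72 and 7.04 in libraries 1 to 6. A gene with 3 counts stood at 0.682 CPM (counts scaled to 1000000 per library) on average in an NKP library, against 0.124 in EILP, 0.137 in ILCP and 0.150 in NK, so low transcripts were measured least precisely in NKP. The 4 populations separated on the first 2 principal components, which held 31.6% and 23.1% of the variance.

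**Figure D1:**
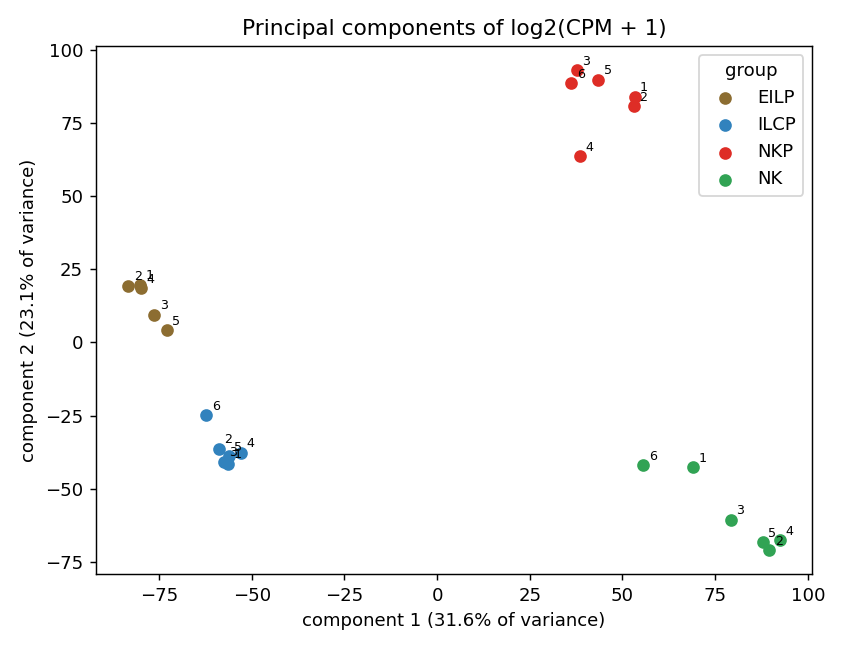
Principal components 1 and 2 of log2(CPM + 1) over the tested genes, 1 point per library, coloured by population; the axis labels give the percent of variance. The 5 EILP, 6 ILCP, 6 NKP and 6 NK libraries form separate groups, with NK 1 and NK 6 nearer to the centre than the other NK libraries.

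Across the 4 populations, Eomes (ENSMUSG00000032446), a T-box transcription factor required for classical NK cells, stood at 13.4 ± 9.55 CPM in EILP (mean ± SD, n = 5), 5.93 ± 2.03 in ILCP, 267 ± 84.6 in NKP and 301 ± 80.4 in NK (n = 6 each). Tbx21 (ENSMUSG00000001444), which encodes the related factor T-bet, stood at 3.40 ± 3.07 CPM in EILP, 5.60 ± 2.57 in ILCP and 81.5 ± 31.1 in NKP, and reached 484 ± 144 CPM in NK. Zbtb16, which encodes PLZF, a factor of innate lymphoid precursors, peaked in ILCP at 184 ± 29.3 CPM and stood at 81.1 ± 15.5 in EILP, 16.1 ± 7.01 in NKP and 3.94 ± 3.80 in NK.

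**Figure D2:**
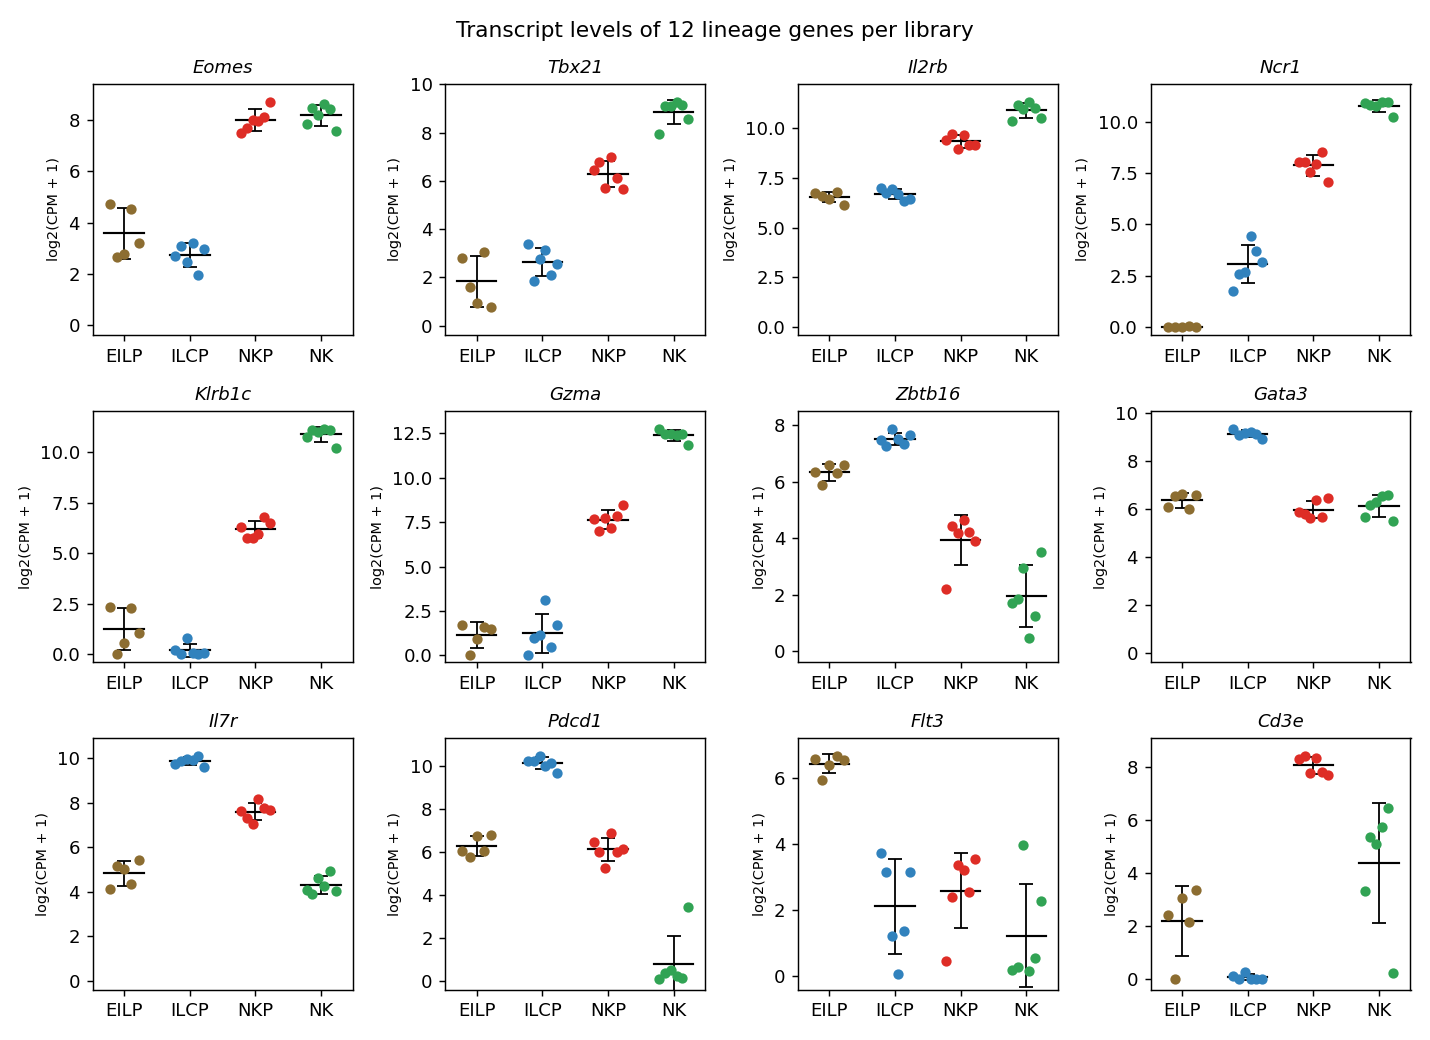
Log2(CPM + 1) of 12 genes of NK, innate lymphoid, progenitor and T cell identity, 1 point per library and population, with a line at the mean and a bar for 1 SD. Eomes stands high in all 6 NKP and all 6 NK libraries, while Gzma and Klrb1c are highest in NK, and Gata3, Il7r, Pdcd1 and Zbtb16 are highest in ILCP.

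NKP libraries were set against EILP libraries to ask which genes mark the NK progenitor relative to the earliest innate lymphoid population. Eomes was 20.01-fold higher in NKP (log2 fold change 4.32 ± 0.43 SE, adjusted p = 2.49e-07), and Tbx21 rose by 4.59 ± 0.57 (adjusted p = 4.63e-06). Il2rb, the beta chain of the receptors for interleukins 2 and 15, was 7.08-fold higher, at 653 ± 141 CPM (n = 6) against 92.6 ± 15.7 (n = 5), and Il7r, the interleukin 7 receptor, rose from 29.1 ± 10.9 to 199.6 ± 54.0 CPM. Ets1, an early NK cell factor, rose by 4.05 ± 0.20, and Ikzf3, a zinc-finger factor of lymphocytes, by 6.17 ± 0.41. Flt3, a receptor of early progenitors, fell by 3.81 ± 0.72, Mycn by 4.62 ± 0.50, Zbtb16 by 2.30 ± 0.28, and Nfil3, a factor needed early in innate lymphoid development, by 3.11 ± 0.23 (adjusted p = 4.11e-09). For each gene named in this paragraph, every NKP library lay on the same side of every EILP library.

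Of the 32 NK receptor genes tested, 26 were higher in NKP, 2 lower and 4 not called (26 and 3 adjusted over the list alone; list test adjusted p = 7.37e-21). Klrb1c, which encodes NK1.1, rose by 5.28 ± 0.77 from 1.90 ± 1.93 to 74.2 ± 22.8 CPM, and Ncr1, the activating receptor NKp46, stood at 243 ± 78.9 CPM in NKP with 1 count over all EILP libraries. Among 23 cytotoxic and cytokine genes, 15 were higher, 2 lower and 6 not called (19 and 2 adjusted over the list alone; adjusted p = 1.83e-12). Gzma, a granzyme, rose by 7.17 ± 0.89, and Ifng was at least 286.3-fold higher, with 308 counts in NKP and 0 in EILP. The NK transcription factors split, with 12 of 20 higher, 5 lower and 3 not called (12 and 6 adjusted over the list alone; adjusted p = 4.83e-05). Irf8, which fell by 3.35 ± 0.37, and Tox, which fell by 1.12 ± 0.14, were among those that dropped. Cytokine receptors had 16 higher, 2 lower and 6 not called of 24 (16 and 2 adjusted over the list alone; adjusted p = 5.11e-10), with Ifngr1 up by 2.94 ± 0.16. Migration receptors had 14 higher, 3 lower and 7 not called of 24 (14 and 4 adjusted over the list alone; adjusted p = 1.28e-11). S1pr1, which guides exit from the marrow, rose by 7.07 ± 0.50, and the chemokine receptor Cxcr6 was at least 6266-fold higher, with no count in EILP. ILC1 and tissue residency genes had 7 higher, none lower and 6 not called of 13 (list test adjusted p = 2.04e-10). Adjusted over the list alone, 8 were higher and 0 lower.

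Stem and early progenitor genes had 1 of 27 higher, 19 lower and 7 not called (2 and 21 adjusted over the list alone; adjusted p = 1.40e-09). Kit, the stem cell factor receptor, fell by 1.77 ± 0.25. Of 24 ILC precursor and helper genes, 10 were higher, 5 lower and 9 not called (10 and 6 adjusted over the list alone; adjusted p = 2.50e-04, and adjusted p = 0.0950 with an estimated correlation). Gata3 (62.6 ± 16.5 against 82.7 ± 17.2 CPM, adjusted p = 0.0798), Id2 (1228 ± 209.8 against 1043 ± 256 CPM, adjusted p = 0.198) and Pdcd1 (73.5 ± 27.7 against 80.6 ± 26.7 CPM, adjusted p = 0.758) overlapped between NKP and EILP and were not called. MHC class I genes had 10 higher, 1 lower and 5 not called of 16 (10 and 2 adjusted over the list alone; adjusted p = 0.00283, and adjusted p = 0.184 with an estimated correlation), with H2-D1 up by 1.06 ± 0.14. Interferon response genes had 9 higher, 1 lower and 10 not called of 20 (9 and 1 adjusted over the list alone; adjusted p = 0.0393, and adjusted p = 0.473 with an estimated correlation). That call ended in 5 of 17 fits with a library left out (adjusted p up to 0.0644), with the replicate block (adjusted p = 0.0715) and with EILP 1 and EILP 4 summed (adjusted p = 0.0626). Glycolysis genes had 9 higher, 1 lower and 8 not called of 18 (10 and 1 adjusted over the list alone; adjusted p = 0.0393, and adjusted p = 0.597 with an estimated correlation). Ribosomal protein genes had 2 higher, 10 lower and 71 not called of 83 (1 and 0 adjusted over the list alone; adjusted p = 0.00310, and adjusted p = 0.780 with an estimated correlation). The ribosomal count depended on the scaling: 56 were lower with library totals alone and 4 with factors from genes above 1 CPM in every group. Of the glycolysis genes, 5 were higher with library totals alone or with upper quartile factors, and the call of the list ended in 4 of 17 fits with a library left out (adjusted p up to 0.0772).

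Of 16 T lineage markers, 14 were higher in NKP, none lower and 2 not called (14 and 0 adjusted over the list alone; adjusted p = 2.46e-15). Cd3d, a chain of the T cell receptor complex, rose by 6.05 ± 0.49, and Cd3e rose from 4.89 ± 3.59 CPM to 271 ± 61.7 CPM. Myeloid markers had 1 higher, 9 lower and 6 not called of 16 (1 and 10 adjusted over the list alone; adjusted p = 0.0229, and adjusted p = 0.472 with an estimated correlation). Mpo, a granule enzyme of myeloid progenitors, stood at 1719.7 ± 218 CPM in EILP, while S100a8, a neutrophil protein, reached 2323 CPM in EILP 1 and 2175 in EILP 4 and at most 11.7 CPM in the other EILP libraries. Mast cell and basophil markers had none higher, 4 lower and 3 not called of 7 (1 and 6 adjusted over the list alone; adjusted p = 0.0318, and adjusted p = 0.441 with an estimated correlation), with Cpa3 down from 827 ± 335 to 186 ± 34.7 CPM. Bone matrix transcripts stood high in every NKP library: 24 osteoblast genes, chosen after their values were seen, held 8.66 ± 2.18% of the counts in NKP and 0.00255 ± 0.00120% in EILP, and all 24 were higher in NKP. Bgn, a matrix proteoglycan, was at least 34987-fold higher, with no count in EILP. Ighm, the immunoglobulin heavy chain, stood at 5398 and 4804 CPM in NKP 1 and NKP 5 and at 474 to 716 CPM in the other NKP libraries. Its rise over EILP was 2.43 ± 0.57, and 0.59 without NKP 1 and NKP 5.

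In total, 3498 genes were higher and 2632 lower in NKP than in EILP, 6130 of 18293 tested, and 2493 and 1474 of them differed by at least 2-fold. With library totals as the only scaling, the split was 2824 higher and 4034 lower, or 41.2% higher against 57.1% in the counts above. The total was 5572 with EILP 1 and EILP 4 summed to 1 sample, 5238 without NKP 1 and NKP 5, and 5495 without the 982 genes that reached 1 CPM in NKP alone. For 3806 genes (20.8%) no NKP library overlapped an EILP library, against 0.433% by chance. Of the 24 lists, 15 were called, and 8 with an estimated correlation.

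**Figure D3:**
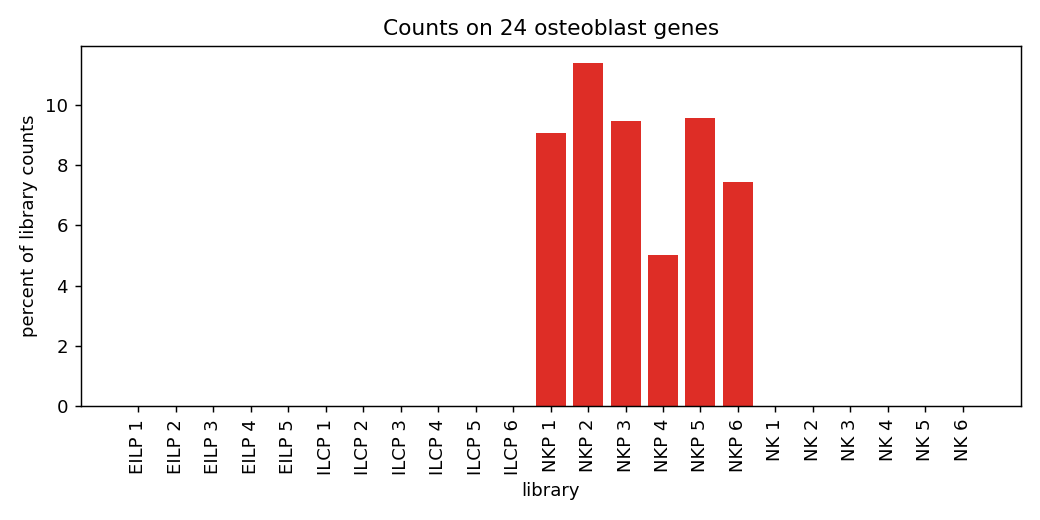
Percent of the deposited counts on 24 osteoblast genes, 1 bar per library, from 0, coloured by population. The 6 NKP libraries lie between 5.03% and 11.4%, and no other library is above 0.00677%.

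ILCP libraries were compared with EILP libraries to ask what separates the innate lymphoid precursor from the early progenitor. Il7r rose 32.6-fold, from 29.1 ± 10.9 (n = 5) to 949.8 ± 109 CPM (n = 6), a log2 change of 5.03 ± 0.26 (adjusted p = 6.85e-11). Gata3, a factor of helper innate lymphoid cells and T cells, rose by 2.76 ± 0.18 to 560.0 ± 52.8 CPM, Rora by 3.79 ± 0.36 to 2252 ± 217 CPM, and Id2, an inhibitor of E proteins, by 1.81 ± 0.15 to 3647 ± 275 CPM. Pdcd1, which encodes PD-1, rose by 3.83 ± 0.27, and Zbtb16 by 1.18 ± 0.27 (adjusted p = 0.00164). Nfil3 fell by 2.44 ± 0.22, Flt3 by 4.05 ± 0.71 and Spi1, the myeloid factor PU.1, by 4.77 ± 0.66. None of these genes overlapped between ILCP and EILP libraries. Eomes was lower in ILCP by a log2 change of -1.18 ± 0.38 (adjusted p = 0.0175) with overlapping libraries. That call ended without EILP 1 (-0.83, adjusted p = 0.0824) or EILP 4 (-0.91, adjusted p = 0.0708).

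Of 24 ILC precursor and helper genes, 21 were higher in ILCP, none lower and 3 not called (21 and 0 adjusted over the list alone; adjusted p = 1.77e-36). Bcl11b, a zinc-finger factor of T cells and innate lymphoid cells, rose by 3.13 ± 0.33, Tcf7 by 0.67 ± 0.10, and Cxcr6 was at least 21711-fold higher, with no count in EILP. The NK transcription factors had 12 of 20 higher, 6 lower and 2 not called (12 and 6 adjusted over the list alone; adjusted p = 3.85e-05), with Ets1 up by 4.91 ± 0.21 and Maf by 5.18 ± 0.25. Tbx21 stood at 5.60 ± 2.57 CPM in ILCP and 3.40 ± 3.07 in EILP and was not called (adjusted p = 0.265). Of 32 NK receptors, 6 were higher, 17 lower and 9 not called (6 and 18 adjusted over the list alone; adjusted p = 0.432). Ncr1 stood at 8.84 ± 6.47 CPM in ILCP with 1 count in EILP. Cytotoxic and cytokine genes had 9 higher, 9 lower and 5 not called of 23 (9 and 9 adjusted over the list alone; adjusted p = 0.432); the list median was 0.47 and the mean -1.27. Xcl1, a chemokine of NK cells, fell by 5.47 ± 0.65 (-6.62 without ILCP 5), and Lta, lymphotoxin, rose by 8.06 ± 0.66. ILC1 and tissue residency genes had 6 higher, 3 lower and 4 not called of 13 (list test adjusted p = 1.31e-06). Adjusted over the list alone, 7 were higher and 3 lower. Migration receptors had 13 higher, 5 lower and 6 not called of 24 (15 and 5 adjusted over the list alone; adjusted p = 2.01e-08), among them the chemokine receptor Ccr2, up by 3.79 ± 0.19. Cytokine receptors had 9 higher, 8 lower and 7 not called of 24 (9 and 9 adjusted over the list alone; adjusted p = 0.00891, and adjusted p = 0.231 with an estimated correlation). The test direction for that list was up while its median was -0.04 and its mean -0.03, and with library totals alone the median was 0.03. With the replicate block its adjusted p was 0.304.

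Stem and early progenitor genes had 1 higher, 17 lower and 9 not called of 27 (1 and 17 adjusted over the list alone; adjusted p = 1.99e-06); Lyl1, a factor of blood stem cells, fell by 5.17 ± 0.47. The S phase list had none higher, 13 lower and 12 not called of 25 (0 and 14 adjusted over the list alone; adjusted p = 3.84e-04, and adjusted p = 0.305 with an estimated correlation). The G2 and M phase list had none higher, 15 lower and 10 not called of 25 (0 and 18 adjusted over the list alone; adjusted p = 2.96e-06, and adjusted p = 0.342 with an estimated correlation). Mki67, a proliferation marker, fell by 1.66 ± 0.33, and Cenpf by 2.54 ± 0.43. Ribosomal protein genes had 1 higher, 79 lower and 3 not called of 83, with a median of -1.20 (1 and 80 adjusted over the list alone; adjusted p = 4.57e-29, and adjusted p = 0.231 with an estimated correlation). Rps21 fell by 1.91 ± 0.26 and Rpl39 by 1.70 ± 0.24. Oxidative phosphorylation genes had 3 higher, 69 lower and 17 not called of 89 (3 and 72 adjusted over the list alone; adjusted p = 2.06e-15, and adjusted p = 0.231 with an estimated correlation). Mitochondrially encoded genes had none higher, 18 lower and 6 not called of 24 (0 and 19 adjusted over the list alone; adjusted p = 3.53e-07, and adjusted p = 0.302 with an estimated correlation), and mitochondrial transcripts took 0.527 ± 0.0638% of the ILCP counts and 1.18 ± 0.168% of the EILP counts. Immediate early and heat shock genes had 1 higher, 9 lower and 8 not called of 18, and 1 and 10 adjusted over the list alone. The list test gave adjusted p = 0.498 with an estimated correlation and adjusted p = 0.0112 with the preset correlation. Left out in turn, single libraries moved that adjusted p from 8.79e-04 (without EILP 1) to 0.0706 (without EILP 5, which ended the call). Fos, an immediate early factor, fell by 6.25 (adjusted p = 7.65e-04), and the EILP libraries were uneven in it, with 8.12 and 8.10 CPM in EILP 1 and EILP 4 and 88.2 to 290.7 CPM in the other 3. No ILCP library was above 5.07 CPM.

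Among markers of other cells, myeloid genes had 1 higher, 13 lower and 2 not called of 16 (1 and 14 adjusted over the list alone; adjusted p = 0.0101, and adjusted p = 0.342 with an estimated correlation). T lineage markers had 7 higher, 4 lower and 5 not called of 16 (7 and 4 adjusted over the list alone; adjusted p = 0.00271, and adjusted p = 0.302 with an estimated correlation). The T cell receptor beta constant gene Trbc1 rose by 2.26 ± 0.11 to 1596 ± 89.5 CPM and Thy1 by 4.67 ± 0.39, while Cd3e stood at 0.0479 ± 0.0841 CPM in ILCP and 4.89 ± 3.59 in EILP. Xist, the RNA of the inactive X chromosome, stood at 265 ± 42.2 CPM in ILCP with 1 count over all EILP libraries, and the Y-linked gene Ddx3y (chosen after the values were seen from a list fixed before) stood at 58.3 ± 9.95 CPM in ILCP and 60.1 ± 22.1 in EILP. NKP libraries also held both, with Xist at 220 ± 19.8 CPM and Ddx3y at 26.8 ± 6.83. The mix of sexes read from these transcripts therefore went with the population in both comparisons against EILP, and changes due to sex are not separated from changes due to population in them.

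In all, 4016 genes were higher and 3814 lower in ILCP than in EILP, 7830 of 18293 tested, 2585 and 2301 of them by at least 2-fold. With upper quartile scaling the balance turned to 3341 higher and 4669 lower (41.7% higher, against 51.3%). Summing EILP 1 and EILP 4 gave 6982. For 5621 genes (30.7%) the libraries of ILCP and EILP did not overlap, against 0.433% by chance. The lists called numbered 14, and 5 with an estimated correlation.

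The NK progenitor was then set against the innate lymphoid precursor, to ask what distinguishes these neighbouring progenitors. Eomes was 45.2-fold higher in NKP, at 267 ± 84.6 against 5.93 ± 2.03 CPM (n = 6 each), a log2 change of 5.50 ± 0.42 (adjusted p = 7.19e-09). Tbx21 rose by 3.87 ± 0.51, Il2rb by 2.67 ± 0.16 and Ncr1 by 4.80 ± 0.41. The chemokine receptor Cxcr3 rose by 5.30 ± 0.52. In the other direction, Zbtb16 fell by 3.48 ± 0.28, Gata3 by 3.15 ± 0.17, Rora by 3.50 ± 0.33, Pdcd1 by 3.94 ± 0.25 (adjusted p = 6.22e-10) and Il7r by 2.24 ± 0.21. No NKP library overlapped an ILCP library in any of these genes.

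Of 32 NK receptors, 28 were higher in NKP, 1 lower and 3 not called (29 and 1 adjusted over the list alone; adjusted p = 5.30e-24). Klrc1, which encodes NKG2A, was at least 7497-fold higher and Klri2 at least 10117-fold higher, each with no count in ILCP. Cytotoxic and cytokine genes had 16 higher, 3 lower and 4 not called of 23 (17 and 5 adjusted over the list alone; adjusted p = 5.52e-09); Gzmb, granzyme B, was at least 619-fold higher, with 658 counts in NKP and 0 in ILCP. ILC precursor and helper genes had none higher, 20 lower and 4 not called of 24 (0 and 21 adjusted over the list alone; adjusted p = 1.02e-24). Il17rb, the receptor for interleukin 25, fell by 5.35 ± 0.38 and Tox2 by 4.64 ± 0.27. The NK transcription factors had 7 higher, 8 lower and 5 not called of 20 (8 and 9 adjusted over the list alone; adjusted p = 0.764), and the list median was 0.18 while the test direction was down. Id2 fell by 1.56 ± 0.14, Tox by 2.08 ± 0.14 and Ets1 by 0.86 ± 0.16. Cytokine receptors had 13 higher, 6 lower and 5 not called of 24 (14 and 6 adjusted over the list alone; adjusted p = 0.00318, and adjusted p = 0.265 with an estimated correlation), with Il21r up by 2.89 ± 0.27.

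In NKP against ILCP, the G2 and M phase list had 16 higher, none lower and 9 not called of 25 (18 and 0 adjusted over the list alone; adjusted p = 2.13e-04, and adjusted p = 0.644 with an estimated correlation), and the S phase list 12, 0 and 13 of 25 (12 and 0 adjusted over the list alone; adjusted p = 0.0184, and adjusted p = 0.644 with an estimated correlation). With library totals as the only scaling these counts were 11 higher for G2 and M phase, and 6 higher and 2 lower for S phase. Without NKP 2 the call of the S phase list ended (adjusted p = 0.0585), and in the other 16 fits with a library left out it held. Birc5, a mitotic survival protein, rose by 1.65 ± 0.37 and Pcna, the sliding clamp of DNA polymerase, by 0.94 ± 0.15. Ribosomal protein genes had 80 higher, none lower and 3 not called of 83, with a median of 0.91 (80 and 0 adjusted over the list alone; adjusted p = 1.04e-17, and adjusted p = 0.562 with an estimated correlation). Rpl38 rose by 1.42 ± 0.24. Oxidative phosphorylation genes had 69 higher, 1 lower and 19 not called of 89 (74 and 2 adjusted over the list alone; adjusted p = 8.93e-13, and adjusted p = 0.393 with an estimated correlation). Mitochondrially encoded genes had 19 higher, none lower and 5 not called of 24 (20 and 0 adjusted over the list alone; adjusted p = 3.53e-05, and adjusted p = 0.601 with an estimated correlation).

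T lineage markers had 9 higher, 2 lower and 5 not called of 16 (10 and 2 adjusted over the list alone; adjusted p = 3.30e-05, and adjusted p = 0.288 with an estimated correlation). Cd3d rose by 8.25 ± 0.51 and Cd3g by 6.85 ± 0.36, while Trbc1 fell by 1.74 ± 0.10. All 24 osteoblast genes were higher in NKP, and Bglap2, an osteocalcin gene, was at least 69901-fold higher, with no count in ILCP. Fgf3, a fibroblast growth factor, stood at 237 ± 40.7 CPM in ILCP and 1.17 ± 2.85 CPM in NKP, where 10 counts were found.

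In total, 3636 genes were higher and 3146 lower in NKP than in ILCP, 6782 of 18293 tested, 2183 and 1680 of them by at least 2-fold. With library totals as the only scaling the split was 2651 higher and 5118 lower (34.1% higher, against 53.6%), the total was 5782 without NKP 1 and NKP 5, and it was 6185 without the 982 genes above. For 3929 genes (21.5%) the libraries did not overlap, against 0.216% by chance. The lists called numbered 10, and 3 with an estimated correlation.

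NK libraries were compared with NKP libraries to ask what changes between the progenitor and the NK cell of the marrow. Eomes did not differ by more than the spread between libraries, at 301 ± 80.4 CPM in NK and 267 ± 84.6 in NKP (log2 change 0.13 ± 0.22, adjusted p = 0.690, n = 6 each). Tbx21 rose 5.74-fold, by 2.52 ± 0.27 (adjusted p = 9.22e-06). The cytotoxic genes Gzma, Gzmb and Prf1, which encode 2 granzymes and perforin, rose by 4.66 ± 0.26, 5.22 ± 0.47 and 4.57 ± 0.42, with Gzma going from 209 ± 79.0 to 5445 ± 1052 CPM. Klrb1c rose by 4.65 ± 0.23, Ncr1 by 2.82 ± 0.22 and Il2rb by 1.53 ± 0.18. Il7r fell by 3.39 ± 0.23, from 199.6 ± 54.0 to 19.5 ± 6.15 CPM. Apart from Eomes, no NK library overlapped an NKP library in these genes.

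Of 32 NK receptors, 29 were higher in NK, none lower and 3 not called (30 and 0 adjusted over the list alone; adjusted p = 1.62e-34); Klrg1, a receptor of mature NK cells, rose by 4.85 ± 0.44. Cytotoxic and cytokine genes had 15 higher, 1 lower and 8 not called of 24 (16 and 1 adjusted over the list alone; adjusted p = 1.46e-13), with Ifng up by 3.04 ± 0.38. The NK transcription factors had 15 higher, 3 lower and 2 not called of 20 (15 and 3 adjusted over the list alone; adjusted p = 9.66e-07, and adjusted p = 0.138 with an estimated correlation). Bhlhe40 rose by 3.83 ± 0.31, Irf8 by 3.17 ± 0.31, Prdm1, which encodes BLIMP-1, by 2.95 ± 0.31 and Nfil3 by 1.56 ± 0.25, whereas Tox fell by 1.33 ± 0.19. Migration receptors had 17 higher, 5 lower and 1 not called of 23 (18 and 5 adjusted over the list alone; adjusted p = 3.20e-04, and adjusted p = 0.138 with an estimated correlation). S1pr5, which NK cells need to leave the marrow, rose by 5.08 ± 0.51, while Cxcr5 fell by 5.41 ± 0.31 and Ccr7 by 4.23 ± 0.73. Cytokine receptors had 10 higher, 3 lower and 10 not called of 23 (10 and 5 adjusted over the list alone; adjusted p = 0.0273, and adjusted p = 0.443 with an estimated correlation). MHC class I genes had 9 higher, none lower and 7 not called of 16 (10 and 0 adjusted over the list alone; adjusted p = 0.00159, and adjusted p = 0.267 with an estimated correlation).

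ILC precursor and helper genes had 2 higher, 14 lower and 6 not called of 22 (2 and 15 adjusted over the list alone; adjusted p = 5.72e-05). Rora fell by 1.71 ± 0.20, Bcl11b by 2.93 ± 0.53 and Tcf7 by 0.89 ± 0.13, while Gata3 stood at 70.9 ± 21.03 CPM in NK and 62.6 ± 16.5 in NKP (adjusted p = 0.697). ILC1 and tissue residency genes had 2 higher, 5 lower and 6 not called of 13, and 3 and 7 adjusted over the list alone. The list test gave adjusted p = 0.0115, adjusted p = 0.138 with an estimated correlation and adjusted p = 0.0547 without NK 1 and NK 6. Of these genes, Cxcr6 fell by 2.02 ± 0.31. Genes linked to Notch and TCF1 had 1 higher, 5 lower and 6 not called of 12 (1 and 5 adjusted over the list alone; adjusted p = 0.0440, and adjusted p = 0.360 with an estimated correlation), a call that ended in 5 of 12 fits with a library left out (adjusted p up to 0.124). Hes1, a Notch target, fell by 3.22 ± 0.24, and Nrarp, another Notch target, rose by 4.95 ± 0.35. Immediate early and heat shock genes had 9 higher, 2 lower and 5 not called of 16, and 10 and 2 adjusted over the list alone. The list test gave adjusted p = 0.0122, and adjusted p = 0.443 with an estimated correlation. NK 6 stood apart in the immediate early gene Jun, at 311 CPM there and at 3.55 to 12.6 CPM in the other NK libraries. Without NK 6 the list had 7 higher and 3 lower, and the change of Jun went from 3.97 ± 1.12 (adjusted p = 0.0155) to 1.10 (adjusted p = 0.0927). Ribosomal protein genes had none higher, 76 lower and 7 not called of 83, with a median of -0.69 (1 and 78 adjusted over the list alone; adjusted p = 3.75e-11, and adjusted p = 0.443 with an estimated correlation). Oxidative phosphorylation genes had none higher, 22 lower and 66 not called of 88 (0 and 22 adjusted over the list alone; adjusted p = 0.00224, and adjusted p = 0.725 with an estimated correlation). The lower genes of that list numbered 31 with DESeq2 size factors, 34 with upper quartile factors, 25 with factors from genes above 1 CPM in every group and 22 with library totals alone. Mitochondrially encoded genes had none higher, 9 lower and 14 not called of 23 (0 and 9 adjusted over the list alone; adjusted p = 0.00180, and adjusted p = 0.516 with an estimated correlation).

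Among markers of other cells, T lineage genes had 1 higher, 11 lower and 2 not called of 14 (1 and 11 adjusted over the list alone; adjusted p = 4.03e-08, and adjusted p = 0.138 with an estimated correlation). Themis, a T cell signalling protein, was at least 939-fold lower, with no count in NK, and Cd3e fell by 2.93 ± 0.72 to 36.6 ± 30.7 CPM. Dendritic cell markers had 2 higher, 11 lower and 1 not called of 14 (2 and 11 adjusted over the list alone; adjusted p = 0.0273, and adjusted p = 0.269 with an estimated correlation, and adjusted p = 0.0717 without NK 1 and NK 6). B lineage markers had none higher, 5 lower and 3 not called of 8 (0 and 5 adjusted over the list alone; adjusted p = 0.0494, and adjusted p = 0.198 with an estimated correlation). That call ended in 6 of 12 fits with a library left out (adjusted p up to 0.102), without NK 1 and NK 6 (adjusted p = 0.0904), without NKP 1 and NKP 5 (adjusted p = 0.0751) and without the 982 genes (adjusted p = 0.138). All 24 osteoblast genes were lower in NK. Erythroid and megakaryocyte markers were not called as a list in any of the comparisons, with 1 of 6 higher here and none lower (1 and 0 adjusted over the list alone; adjusted p = 0.634). The G2 and M phase list had no called member among 25, and Mki67 stood at 575 and 517 CPM in NK 1 and NK 6 and at 52.0 to 94.9 CPM in the other NK libraries.

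In all, 2119 genes were higher and 2261 lower in NK than in NKP, 4380 of 15753 tested, 1082 and 1573 of them by at least 2-fold. With upper quartile scaling the split was 1662 higher and 2779 lower (37.4% higher, against 48.4%). The total was 5788 without NK 1 and NK 6, 3147 without NKP 1 and NKP 5, and 3893 without the 982 genes above. Without these 982 genes the balance turned to 1993 higher and 1900 lower (51.2% higher). Tested against a 2-fold change, with all genes kept, 330 were higher and 917 lower (26.5% higher). For 2528 genes (16.0%) the libraries did not overlap, against 0.216% by chance. The lists called numbered 16 (7 higher and 9 lower) and 3 with an estimated correlation. Without NK 1 and NK 6 they numbered 13 (7 higher and 6 lower). The lists of ILC1 and tissue residency genes, dendritic cell markers and B lineage markers were then no longer called.

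**Figure D4:**
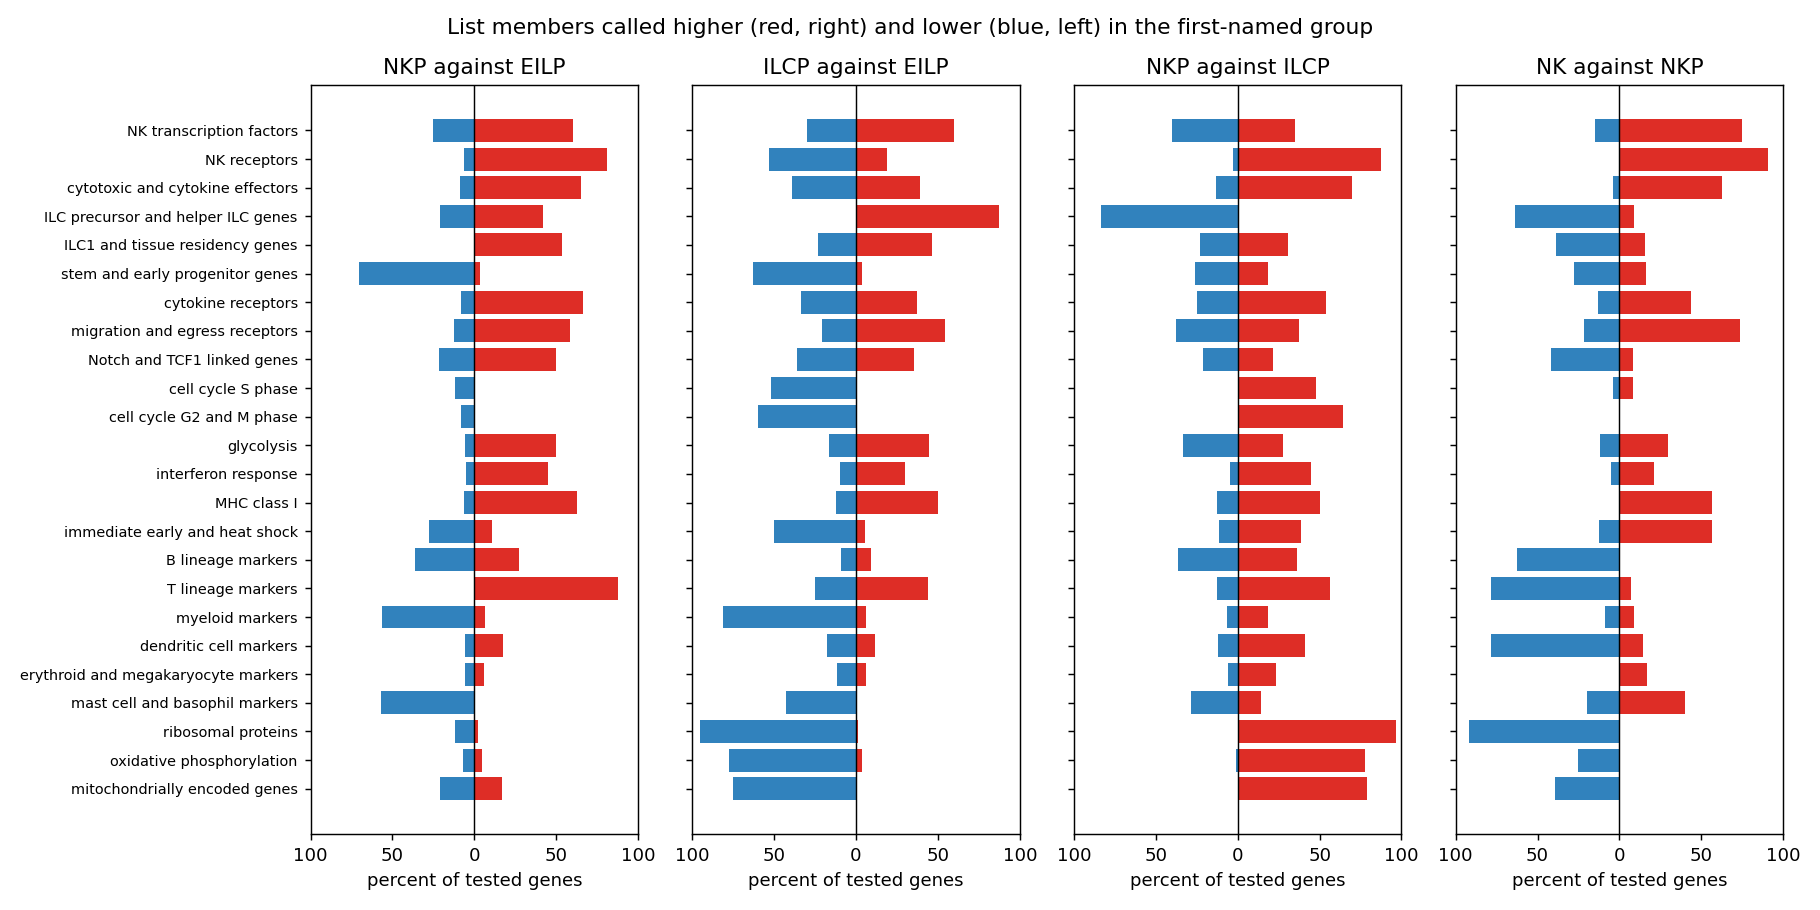
Percent of the tested members of each gene list called higher (to the right, red) or lower (to the left, blue) in each of the 4 comparisons. NK receptors were mostly higher in NKP and higher again in NK, ILC precursor and helper genes were mostly higher in ILCP, and ribosomal protein genes were mostly lower in ILCP than in EILP.

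The changes of NKP and ILCP relative to EILP were set side by side to ask how far both progenitors depart from EILP in the same genes. Of 18293 genes, 1903 were called higher in both and 1398 lower in both, Il7r and Ets1 among the former and Flt3, Irf8 and Nfil3 among the latter. A further 428 were called in opposite directions, among them Zbtb16, which was higher in ILCP and lower in NKP. Independent lists of the same sizes would share 768 higher and 549 lower genes. Because the same EILP libraries served both comparisons, unchanged groups were simulated against them. Over 10 runs this gave a correlation of 0.532 and a covariance of 0.157. No gene was called in either simulated comparison. The simulation therefore cannot show how many of the shared calls come from the shared libraries. The observed correlation of log2 fold changes was 0.462 and the covariance 1.76, which was 1.60 above the simulated covariance. With the EILP libraries split between the comparisons, 2114 and 1615 genes were called in the same direction, 250 and 416 in opposite directions, and the correlations were 0.365 and 0.219. The same-direction count of 3301 was 2788 with EILP 1 and EILP 4 summed and 2911 without NKP 1 and NKP 5.

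The difference of NKP from ILCP was set beside that of NK from NKP, to ask which genes were called in the same direction. Each difference is named a step below, but whether ILCP gives rise to NKP was not tested. Of 15590 genes tested in both, 632 were called in the same direction in both steps, 395 higher and 237 lower, and 2027 in opposite directions. Tbx21, Ncr1, Gzmb and Il2rb rose in both steps, and Il7r, Rora and Tcf7 fell in both. Of the genes with opposite calls, 1375 were higher in NKP than in ILCP and lower again in NK, as Cd3e was, and 652 were lower and then higher, such as Nfil3, whose first call ended without NKP 1 and NKP 5 (adjusted p = 0.0769). Independent lists would give 453 and 398 genes in the same direction, and 496 and 364 in opposite directions. NKP libraries stand on both sides with opposite sign, and unchanged groups simulated in that way gave a correlation of -0.521 and a covariance of -0.114. The observed values were -0.575 and -2.01, and the covariance lay -1.89 from the simulated one. With the NKP libraries split between the steps in 2 ways, which leaves fewer samples in each, the correlations were -0.470 and -0.470. The opposite calls then numbered 1400 and 1331 of 18039 genes, and those in the same direction 498 and 427. Genes higher and then lower numbered 1150 and 1052 in these splits, where independent lists would give 360 and 349. Genes lower and then higher numbered 250 and 279, against 181 and 161 by independent lists, so that the 652 fell by more than the 1375. Without the genes that reached 1 CPM in NKP alone the opposite calls numbered 1636 and the correlation was -0.269. Of these calls, 984 were higher and then lower and 652 lower and then higher, so only the former fell. Leaving out that set does not remove all bone matrix transcripts. Sparc, at 3.93 CPM in NK, and Col1a1, at 2.51 CPM in EILP, stayed in. The same-direction count was 436 without NKP 1 and NKP 5 and 747 without NK 1 and NK 6.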

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

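Of the tests in this part, only the covariation of the osteoblast genes was fixed before the result that it measures was seen, and all other tests were chosen after it. For each comparison, the libraries were also regrouped in 100 splits that included the real one, and in each case 1 split, the real one, called as many genes as reported. The highest number of calls among the other splits was 2667 for NKP against EILP, 4398 for ILCP against EILP, 301 for NKP against ILCP and 3 for NK against NKP.

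Bone matrix transcripts in NKP stood out, with Sparc at 27886 ± 10204 CPM, Col1a1 at 18779 ± 5141 and Bglap at 6642 ± 2314 over 6 libraries. Low depth was excluded, as the lower share among the 2 deepest NKP libraries was 5.03%, and the highest among the 17 libraries of other populations was 0.00677%. Genes of marrow stroma and endothelium in general summed to at most 0.214% of the osteoblast sum. The 24 osteoblast genes were chosen after their values were seen, so this low ratio cannot exclude a contribution of these cells. Of 6 tested reticular stroma genes, 3 were higher in NKP than in EILP and 1 was lower. Osteoblast-lineage cells or their RNA as a single source may account for the bone matrix transcripts. Over the NKP libraries the 24 genes had a mean correlation of 0.584, against 0.0861 at the 95th percentile of 1000 matched random sets. Those sets left out the 982 genes that stood under 1 CPM in all groups but NKP. The test therefore cannot tell a single osteoblast source from variation common to genes found only in NKP. Whether the sorted cells themselves made these transcripts was not tested and stays open.

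T cell receptor complex transcripts were a second pattern, with Cd3e at 271 ± 61.7 CPM and Trdc at 782 ± 85.2 in NKP, against 36.6 ± 30.7 and 218 ± 75.6 in NK. CD4 or CD8 T cells in the sort were excluded as the source, as Cd4, Cd8a and Cd8b1 summed to at most 2.46% of Cd3e in an NKP library. T cells without CD4 and CD8, as a varying minority, remain a candidate explanation. The mean correlation of 5 receptor complex genes over the NKP libraries was 0.384, against 0.339 at the 95th percentile of 1000 matched random sets. Cd3d, at 478 ± 45.7 CPM, and Cd3g, at 469 ± 67.7, differed little between the NKP libraries, which limits what this correlation can show. Transcription of these genes by the NK progenitor itself could give the same covariation, and the tables do not separate the 2.

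Ribosomal protein transcripts in ILCP fell relative to EILP with a list median of -1.20. The choice among the scalings used here did not account for it: the list median lay between -1.35 and -1.12 under the 4 others. Those scalings put the median of all genes only between -0.151 and 0.0708, so a larger error of scale was not tested. A first form of this test, relative to all genes, was dropped because scaling cancels in it. Short transcripts could account for a part: genes matched on transcript length (median 810 against 771) and on level had a median of -0.58, with 1000 drawn sets between -0.93 and -0.18, which does not decide it. A first run with summed exon lengths, which put the ribosomal genes at a median of 1781, gave -0.24 with a range of -0.65 to 0.08, and it was replaced because that measure did not suit these genes. The same matching for the oxidative phosphorylation list, with a median of -0.89, gave -0.53, with 1000 drawn sets between -0.79 and -0.15. That does not decide it for this list either. A biological change of translation in ILCP, the population the design gives as the difference, was not tested apart from transcript length.

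Single libraries far from the rest of their group were searched for with Dixon's ratio at its 95% limit in 85 genes that the text names, where the mean was at least 5 CPM, and in 6 measures of the libraries. It marked 26 of 272 groups. Chance flags about 1 in 20 groups where values are normally distributed, which CPM values need not be. Several flags also fell on the same library, so the excess over 1 in 20 is not a test. Among EILP libraries, EILP 5 stood apart in Ccr2 (60.1 CPM, nearest 44.7) and EILP 2 in Prg2 (700.4 CPM, nearest 1013). Among ILCP libraries, ILCP 6 stood apart in Nfil3 (29.2 CPM, nearest 58.6) and Xist (348.5 CPM, nearest 266.6), ILCP 1 in Mcpt8 (226.9 CPM, nearest 1.11) and ILCP 4 in Pf4 (78.2 CPM, nearest 1.24). NKP 2 stood apart in Hba-a1 (61.5 CPM, nearest 1.305), NKP 4 in Mpo (1191 CPM, nearest 44.2), NKP 5 in Il21r (17.3 CPM, nearest 37.2) and Pcna (346.3 CPM, nearest 260.3), and NKP 6 in Nfil3 (59.8 CPM, nearest 36.9) and Xcl1 (200.9 CPM, nearest 120.4). NK 6 stood apart in Fos (503.7 CPM, nearest 29.7), Id2 (1386 CPM, nearest 1989), Jun (310.8 CPM, nearest 12.6), Klri2 (277.9 CPM, nearest 513.8), Mpo (786.7 CPM, nearest 68.8), Ncr1 (1179 CPM, nearest 1720) and Prg2 (2486 CPM, nearest 0.0561), and in the share of its 20 most abundant genes (6.95%, nearest 8.58%). NK 1 stood apart in Hba-a1 (27.9 CPM, nearest 1.98), Xist (347.6 CPM, nearest 77.03), depth (40.9, nearest 21.7, in units of 1000000 counts) and genes detected (26079, nearest 22521). NK 5 stood apart in Mcpt8 (186.3 CPM, nearest 7.58) and NK 4 in the share of osteoblast genes (0.00677%, nearest 0.00257%).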

How the results depend on the processing

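The tests of this part were planned before the data were examined, except the sum of EILP 1 and EILP 4, the fits without NKP 1 and NKP 5, without NK 1 and NK 6 or without genes near 0 outside NKP, the factors from genes above 1 CPM in every group, and the fit of all 23 libraries, which were chosen after. Of the counts of genes and lists, 81 stayed within 1.5 times their first value under the alternatives and 10 did not, which are given below; with a library left out, all 166 stayed within it. Left out in turn, single libraries moved the calls from 5509 to 6469 for NKP against EILP, 6905 to 8106 for ILCP against EILP, 6097 to 7149 for NKP against ILCP and 3765 to 4926 for NK against NKP. The genes called in the same direction in NKP and ILCP against EILP ranged from 2752 to 3639. Those called in the same direction in NKP against ILCP and in NK against NKP ranged from 532 to 665. Of 5732 gene results under the alternatives, 5458 kept direction and side of the threshold, 241 lost the call, 23 gained it and 10 reversed. Depth limits the low transcripts of NKP, whose 3-count floor reached 2.33 CPM in NKP 3.

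Tested against a 2-fold change, which asks for more than a difference from 0, the calls were 2297, 2090, 1932 and 1247 in the order above. With an estimated correlation, the lists called fell from 15 to 8, 14 to 5, 10 to 3 and 16 to 3, because the test then carries the correlation between the members. The genes shared by NKP and ILCP fell from 3301 to 2114 and 1615 when the EILP libraries were split, which leaves fewer samples in each comparison. With the replicate number as a block the calls were 6019, 7743, 6647 and 4158. For libraries of equal number, the deviations from the group means correlated at -0.16 to 0.20. The highest value was that of NKP 6 with ILCP 6, which was the best match of NKP 6 among the ILCP libraries. These correlations show no general pairing by number but cannot exclude one.

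For the reversals below the cause was not tested. NKP against EILP: Pdcd1 was 0.036 with limma-voom and between -0.301 and 0.037 with a library left out, and Hba-a1 between -0.365 and 3.843. ILCP against EILP: Il2rb was -0.005 with upper quartile factors, Gzma -0.682 with limma-voom and -0.693 to 0.771 with a library left out, and Pf4 -0.16 to 5.789. Ifng had no count in EILP and 3 in ILCP, all in ILCP 2, so its fitted value, 0 without that library and up to 2.361 otherwise, gives no fold and no change of direction. NKP against ILCP: Flt3 was -0.028 with library totals and -0.023 to 0.711 with a library left out, Ighm -0.447 without NKP 1 and NKP 5, Mpo -2.067 with the block and -4.008 to 1.706 with a library left out, and Mcpt8 -5.237 to 1.027. NK against NKP: Eomes was -0.012 and Gata3 -0.004 with upper quartile factors, Mki67 -0.712 without NK 1 and NK 6, Mcpt8 -0.457 with limma-voom, and Mpo -3.721 to 3.821 with a library left out.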

Other observations

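The tests and lists of this part were chosen after the values were seen, except the list of sex-linked genes, which was fixed before and from which Ddx3y was chosen after. Fgf3 and Fgf15, neighbouring fibroblast growth factor genes, were expressed in EILP and ILCP. Fgf3 stood at 109 ± 8.40 CPM in EILP and 237 ± 40.7 in ILCP, and Fgf15 at 39.9 ± 12.6 and 163 ± 31.4. In NKP and NK, Fgf3 stood at 1.17 ± 2.85 and 0.344 ± 0.658 CPM and Fgf15 at 0.178 ± 0.436 and 0.0227 ± 0.0266. A list of 6 genes at that site, 5 of them tested, summed to 173 ± 22.7 CPM in EILP, 494 ± 85.7 in ILCP, 1.46 ± 2.76 in NKP and 0.394 ± 0.661 in NK. All 5 were higher in ILCP than in EILP and lower in NKP than in either.

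Lists of other marrow cells gave summed levels for EILP, ILCP, NKP and NK. Osteoclast genes stood at 114 ± 67.3, 61.0 ± 48.8, 445 ± 217 and 849.9 ± 127 CPM, chondrocyte genes at 0.544 ± 0.206, 1.56 ± 1.80, 177 ± 269.8 and 2.24 ± 1.92, reticular stroma genes at 139.7 ± 71.4, 9.96 ± 9.23, 38.9 ± 38.5 and 19.7 ± 31.7, and endothelial genes at 3.28 ± 0.815, 1.74 ± 2.14, 1.44 ± 1.06 and 1.51 ± 1.89. Single genes carried several of these sums. In NK, Car2 stood at 715 ± 149 CPM and Acp5 at 134 ± 40.3, and all other osteoclast genes were under 1 CPM. In NKP, Car2 and Acp5 stood at 219 ± 132 and 211 ± 105 CPM. In EILP, the reticular stroma gene Hp stood at 138 ± 71.0 CPM, while Cxcl12 and Lepr had no count. In NKP, Cxcl12 and Lepr stood at 15.4 ± 21.2 and 4.77 ± 3.07 CPM. The sums alone therefore do not show these cell types. Between NKP and EILP, 1 of 3 tested osteoclast genes, 3 of 3 chondrocyte genes, 3 of 6 reticular stroma genes and 4 of 5 plasma cell genes were higher in NKP, and 1 reticular stroma gene and the only tested endothelial gene were lower. Plasma cell genes took 1.54% of the counts in NKP 1 and 1.38% in NKP 5 and at most 0.0918% in the other NKP libraries. Igkc, an antibody light chain, stood at 8806 and 9509 CPM in NKP 1 and NKP 5 and at most 11.1 CPM in the other NKP libraries.

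Sex-linked transcripts differed between populations and, in NK, between libraries of 1 population. Xist stood at 348 CPM in NK 1, where Ddx3y had no count, and at 0.238 CPM in NK 6, where Ddx3y stood at 78.0 CPM, while NK 2 to NK 5 held 46.2 to 77.03 CPM of Xist and 43.4 to 49.5 CPM of Ddx3y. ILCP and NKP libraries held both transcripts, with Ddx3y at 44.7 to 68.4 CPM in ILCP and 20.6 to 35.7 CPM in NKP. EILP libraries held Ddx3y at 41.2 to 96.9 CPM and Xist at no more than 0.0362 CPM. Both comparisons against EILP therefore also differ in the sexes that these transcripts show. NKP against ILCP and NK against NKP were not matched in these transcripts either, so sex is not separated from population there.

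Prg2, an eosinophil granule protein, stood at 993 ± 169 CPM in EILP, at 2486 CPM in NK 6 and at no more than 0.0561 CPM in NK 1 to NK 5.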
